A study of Mus musculus with 17 samples.

How the data were processed

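Total RNA of mouse hippocampus was sequenced in 17 libraries from 16-month-old wild-type C57BL/6J mice. Per the labels' protocols, mice were tested in the Y maze and the open field 24 h before abdominal surgery, in which the small intestine was handled and restored. They were tested again at 24 h, 3 days, 7 days or 1 month, and the hippocampus was then collected under anaesthesia after perfusion. Operated mice were described as having postoperative cognitive dysfunction, a decline in memory and attention after surgery. Control mice had no surgery. Whether they were tested in the mazes shortly before collection is not given in the sources used here. The groups were control (CON, n = 4) and 24H (n = 3), 3D (n = 3), 7D (n = 3) and 1M (n = 4) after surgery, so 13 libraries were from operated mice. Libraries keep the replicate numbers of the labels, as in CON 5. The labels do not say that each library came from its own mouse, and the p-values here measure spread between libraries. The titles of 3 of the 4 libraries of the 1M group read 2mps, 3mps and 4mps, which can be read as later months, and their other fields give 1 month, which was used. The time of these 3 is therefore in doubt.

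The libraries were made with a TruSeq RNA kit and a VAHTS Universal V6 kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.4, R 4.2.1, edgeR and the builds mm10 and GRCm38.p4, with no order. The counting tool, the strand setting and any filter are not given in the sources used here. The deposited table holds expected counts per gene name, as judged from its values: whole numbers except for 40 genes with fractions, and unequal library totals. The table lists 16885 genes, each above 0 in at least 16 of the 17 libraries, and 16438 in all of them. Il1b, Il6 and Tnf are among genes that are not listed. Date numbers written by a spreadsheet replace the names of 23 genes, which hold at most 0.183% of a library's counts. Library totals ran from 1.52e+07 to 2.94e+07 counts, and the most abundant gene took at most 2.61% of a library.

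Counts were rounded to whole numbers and fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr by group). All 17 libraries were in 1 fit with 1 coefficient per group and no covariate, which left 16200 genes tested. Genes were called at a Benjamini-Hochberg adjusted p (FDR) below 0.05. Each time was compared with control, each time with the one before it, and all 5 groups in a joint test. Log2 fold changes carry their standard error (SE), and group levels are normalised CPM as mean and standard deviation (SD). Log2 CPM used a prior count of 2. A level of 1 CPM is between 15.2 and 29.4 counts in a library, which limits the precision of genes as low as Gbp7. Gene positions are from GENCODE M21 on GRCm38, and 16169 listed symbols matched 1 gene there. Reads of genes that overlap or resemble each other, such as Hspa1a and Hspa1b, the Gbp family and ribosomal protein genes, can be shared among them.

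A total of 38 gene lists of cell type markers, response programmes and a sex check were tested where at least 5 members were tested. Camera of limma 3.58.1 compared each list with all other genes at a preset inter-gene correlation of 0.01, adjusted over 148 tests (37 lists in 4 comparisons with control). It was repeated with an estimated correlation, under which none of the 148 passed, nor any with the library set as a term (lowest adjusted p = 0.192 and 0.182). Counts of called members are over all genes tested, and a second count is adjusted over the list alone. The lists, the tests, the comparisons and the rule for naming genes were fixed before the data were examined. That rule took, for each comparison with control, up to 8 risen and 8 fallen genes of lowest adjusted p among called genes with an average log2 CPM of at least 1 and non-overlapping libraries. It took 4 and 4 for neighbouring times, 10 for the joint test, up to 3 members of lowest p of each list described, and Ttr. Where fewer than 3 genes were called in a direction, up to 3 of lowest p were named as not passing. Genes with provisional names were passed over. The value of 1 list member that the rule took is not reported here. Other genes named were chosen after their values were seen, as were the lists described for each comparison. Ttr was chosen by the study on these samples.

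The libraries formed 2 sets that the labels do not name. The alternatives built on them were chosen after the data were seen: the set as a term, each set alone, the set with a choroid plexus score, and a fit without the 6 libraries with a score above 2. The score is the mean log2 CPM of the choroid plexus list without Ttr. The other alternatives were RLE size factors, library totals, no count filter, a stricter filter at 1 CPM, DESeq2 1.42.0, limma voom with quality weights, the compared groups alone, the replicate number as a block, the choroid plexus score alone as a covariate, an added log2 fold change of 1, and leaving out each library in turn. A check on simulated data with 200 changed genes per comparison recovered 80% of 2-fold changes at 24H and at 7D, 79% at 3D and 87% at 1M, in the right direction. Of 1.5-fold changes it recovered 53% at 24H, 61% at 3D, 50% at 7D and 48% at 1M, all without the set as a term. False calls at 1M were 18 of 153 without and 5 of 149 with the set as a term, and between 3D and 7D 1198 of 1343 and 6 of 104. A library left alone in a group was assumed to vary as the others do. Sex was checked by Xist, which stayed between 0.057 and 0.813 CPM, and Ddx3y, which stayed between 31.3 and 63.7 CPM in every library. Behaviour scores and protein measurements were not analysed here.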

Results

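The question named by the study is which hippocampal transcripts follow abdominal surgery in aged mice with postoperative cognitive dysfunction, with transthyretin (Ttr) as a proposed marker. Fos, Arc, Junb, Per1 and Sik1, which neurons induce within minutes to hours of activity, were higher after surgery and passed the test 1 month later. Drp2, which encodes a dystrophin-related protein, was lower in 13 of 13 operated libraries than in 4 of 4 controls. It was picked for its low p from 16200 genes tested, and how many of them part the libraries this way was not counted. Ttr passed at no time by edgeR.

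The libraries fell into 2 sets that the study's groups did not explain. The deeper set held 7 libraries (CON 1, CON 2, 24H 2, 24H 3 and the 3 of 7D) with 2.18e+07 to 2.94e+07 counts. The shallower set held 10 libraries (CON 4, CON 5, 24H 4, the 3 of 3D and the 4 of 1M) with 1.52e+07 to 1.89e+07 counts. The first principal component carried 29.3% of the variance and the second 8.42%, and clusters of rank correlation split the libraries the same way, with 0 libraries placed differently. With the 5 groups accounted for, 4830 genes differed between the sets by edgeR at an FDR of 0.05, 2413 higher and 2417 lower in the shallower set. Between the 2 and 2 control libraries, 3278 of 15982 genes differed. The set difference is estimated from the control and 24H libraries, the groups that both sets hold. Among these, choroid plexus genes were lower in the shallower set by a list median log2 difference of -2.66. Hemoglobin and other red cell genes were higher by 3.22. Leptomeningeal genes were lower by a median of -1.08, and microglial (0.43), damage-associated microglial (0.53) and oligodendrocyte genes (0.39) were higher. None of these 6 lists passed with an estimated correlation (adjusted p from 0.298 to 0.656). Mitochondrial genes held 6.25 to 7.31% of counts in the deeper set and 5.36 to 6.22% in the shallower. The common dispersion was 0.0261 without and 0.0179 with the set as a term. Values with the set as a term, or within a set, are therefore given beside many of the values without it, and all are in the tables. The 3D and 1M groups lie in the shallower set alone and the 7D group in the deeper set alone. With the set as a term, their values carry over the set difference of the control and 24H libraries. The choroid plexus score did not follow the sets in these groups. It was 0.472, 1.06 and 1.24 in the deeper 7D libraries, and ran from 1.06 in 1M 4 to 3.65 in 1M 1 over the shallower 3D and 1M libraries.

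**Figure D1:**
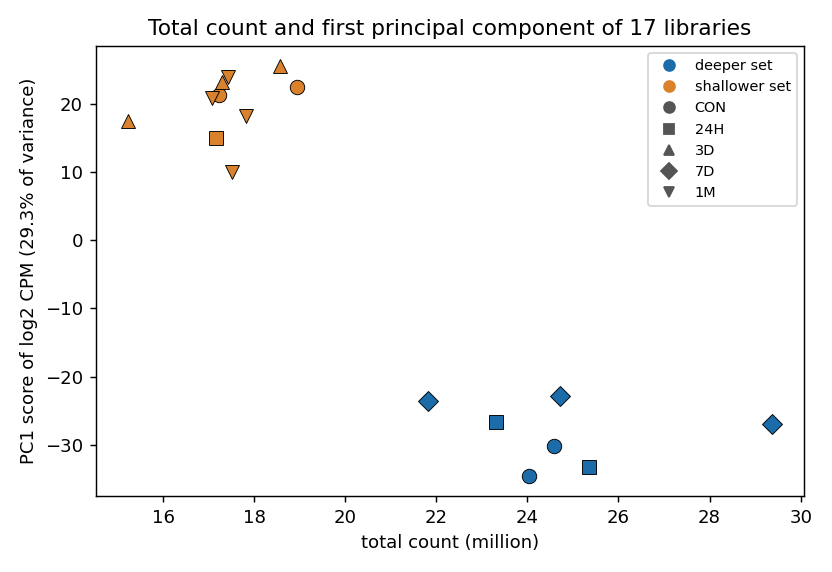
Total count of each of the 17 libraries against its score on the first principal component, coloured by set, with marker shape by group. The 7 libraries of at least 2.18e+07 counts lie apart from the 10 libraries of at most 1.89e+07 counts, and both sets hold control and 24H libraries.

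Ttr, on chromosome 18 from 20665280 to 20674321 on the plus strand, encodes the carrier of thyroxine and retinol-binding protein and is made by the choroid plexus. It averaged 958 ± 1229 CPM (SD, n = 4) in controls, 696 ± 711 CPM (n = 3) at 24H, 102 ± 14.9 CPM (n = 3) at 3D, 23.7 ± 22.9 CPM (n = 3) at 7D and 575 ± 733 CPM (n = 4) at 1M. Single control libraries ran from 41.1 CPM in CON 4 to 2658 CPM in CON 2, a spread as wide as that between groups. Against control the log2 fold change was -0.46 ± 1.43 (SE, adjusted p = 0.963) at 24H, -3.24 ± 1.61 (0.398) at 3D, -5.32 ± 1.80 (0.347) at 7D and -0.74 ± 1.32 (0.797) at 1M, none past the threshold. The values with the set as a term were -0.66 (0.904), 0.78 (0.941), -6.18 (0.119) and 3.28 (0.355), so the direction at 3D and 1M depended on the set. Within the deeper set all 3 libraries of 7D, at 3.36, 19.3 and 48.5 CPM, lay below CON 1 at 1063 CPM and CON 2. Within the shallower set the 3 libraries of 3D, from 86.7 to 117 CPM, lay above CON 4 and above CON 5 at 68.5 CPM. Without CON 2 the log2 fold change at 24H was 0.83 and that at 1M was 0.55, the opposite direction. By DESeq2, Ttr passed at 7D alone, at -5.34 (adjusted p = 0.0446), and its adjusted p over the alternatives ran from there to 1.00. Ttr was chosen by the study on these samples. Of the next most abundant choroid plexus genes, Enpp2 had a median of 470 CPM, Kl of 66.7 CPM, Car12 of 57.9 CPM and Slc29a4 of 47.4 CPM in the 6 libraries with a choroid plexus score above 2 (CON 1, CON 2, 24H 2, 24H 3, 1M 1 and 1M 3), against 136, 33.0, 44.0 and 51.3 CPM in the other 11, so Slc29a4 was not higher there. Of the 29 members of the list, 12 were at 1 CPM or more in each of those 11 libraries, and 1, Ttr, is on another list too.

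**Figure D2:**
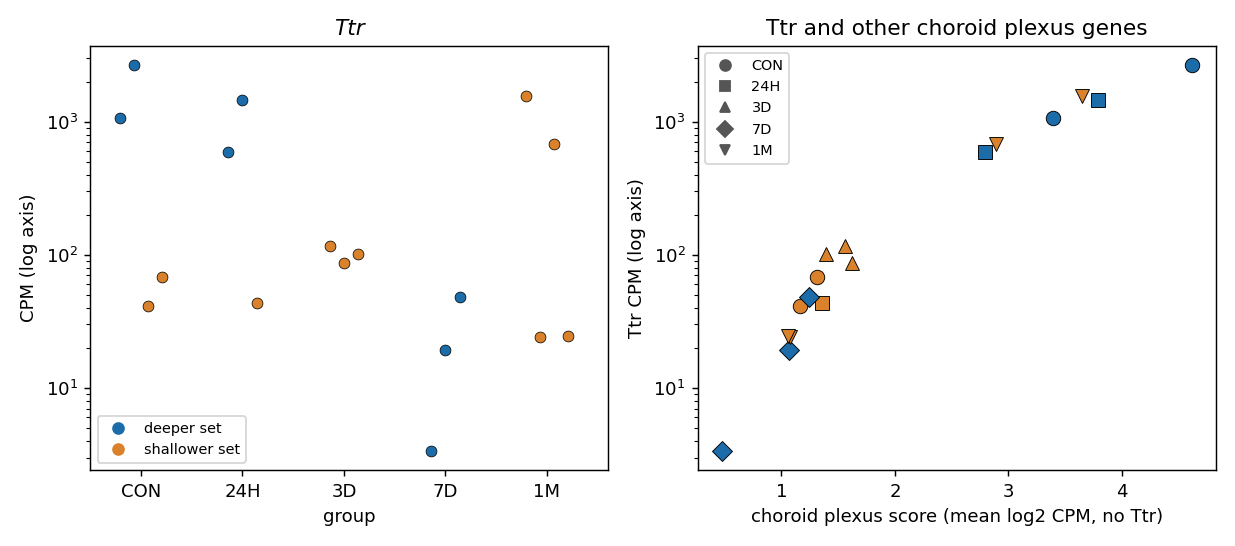
Ttr in each of the 17 libraries in CPM on a log axis by group, and against the choroid plexus score, the mean log2 CPM of the other choroid plexus genes. Libraries of the 1M group run from 24.0 to 1572 CPM and controls from 41.1 to 2658 CPM, and Ttr is high in the libraries of high score.

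At 24 h after surgery, Drp2 was the 1 gene called. It lies on chromosome X from 134404551 to 134456573 on the plus strand and fell to 44.3 ± 4.22 CPM (SD, n = 3) from 91.3 ± 10.1 CPM (n = 4) in controls, a log2 fold change of -1.04 ± 0.13 (SE, adjusted p = 0.0146). Adding the set as a term gave -1.07 (0.00881). It was -1.03 (0.0503) within the deeper and -1.13 (0.132) within the shallower set, the latter with 1 library of 24H. The call was lost without CON 1 (adjusted p = 0.0575), CON 4 (0.0693) or 24H 3 (0.102). It was also lost with the compared groups alone and with the replicate number as a block, which called 0 genes each. Genes of lowest p that did not pass (adjusted p = 0.452) included the stress-induced Tiparp at 0.63 ± 0.12, the kinase gene Sik1 at 0.74 ± 0.15 and Fos at 1.00 ± 0.22. Lower and not passing were Vangl2, a planar polarity gene, at -0.54 ± 0.10, Stard8 at -0.46 ± 0.09 and Mfsd4 at -0.34 ± 0.07. By edgeR, 960 genes had an unadjusted p below 0.05. DESeq2 called 12 and voom 5, the deeper set alone 7 and the shallower alone 38. The count was 2 without CON 2, 3 without 24H 2 and 6 without 24H 4.

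Immediate early genes as a list were higher at 24H, with a median log2 fold change of 0.51 and 23 of 25 members higher. Examples were Fos at 1.00 ± 0.22 (SE, n = 3 and 4), Sik1 at 0.74 ± 0.15 and Per1 at 0.38, and 12 members passed when adjusted over the list alone, with none over all genes. Camera gave an adjusted p = 3.02e-16, and adjusted p = 0.316 with an estimated correlation. The median was 0.54 with the set as a term, 0.78 within the deeper and 0.20 within the shallower set. Chaperone and unfolded protein genes such as Hspa5 at 0.74 ± 0.23, Dnajb1 at 0.43 and Dnajb11 at 0.35 had 26 of 28 members higher (median 0.30, adjusted p = 4.68e-08, and adjusted p = 0.538 with an estimated correlation). Their median was 0.29 with the set and -0.04 within the shallower set. Glucocorticoid targets had 24 of 25 members higher (median 0.30, adjusted p = 4.43e-08, and adjusted p = 0.538 with an estimated correlation), 7 of them when adjusted over the list alone. Among them were Tsc22d3 at 0.66 ± 0.17, Pdk4 at 0.61 ± 0.16 and Angptl4 at 1.23 ± 0.36. The median was 0.34 with the set and 0.13 (0.0337) without 24H 4.

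Myelin genes of oligodendrocytes were lower at 24H in 19 of 20 members (median -0.37, adjusted p = 4.68e-08, and adjusted p = 0.538 with an estimated correlation). Opalin at -1.29 ± 0.29 (SE, n = 3 and 4) passed when adjusted over the list alone, and Mog at -0.54 and Aspa at -0.50 did not. The list's median was -0.27 with the set, -0.07 (adjusted p = 0.335) within the deeper set and -0.24 without 24H 3. Interferon-induced genes such as Ifi27l2a at -1.24 ± 0.49, Bst2 at -0.64 and Ifit3b at -0.58 were lower in 23 of 24 members (median -0.23, adjusted p = 9.31e-05, and adjusted p = 0.538 with an estimated correlation). Their median was -0.24 with the set, -0.06 (0.143) within the deeper set and -0.64 within the shallower set, with 1 library of 24H. It was -0.13 (0.236) without 24H 4, -0.13 (0.00225) without CON 5 and -0.10 (0.0624) with voom. Microglial identity genes such as Gpr34 at -0.36, Cx3cr1 at -0.31 and Sall1 at -0.22 were lower in 19 of 20 (median -0.23, adjusted p = 6.91e-05, and adjusted p = 0.538 with an estimated correlation). The microglial median was -0.14 with the set, -0.05 (0.658) within the deeper set and -0.12 without CON 5. Choroid plexus genes, 27 of 29 lower, had a median of -0.40 that camera did not call (adjusted p = 0.876), with Aqp1 at -0.84, Slc29a4 at -0.19 and Car12 at -0.17. Without CON 2 the choroid plexus median was 0.68 (0.00906), and it passed in the lower direction without CON 4 (-0.69, 0.0371), CON 5 (-0.64, 0.0475) or 24H 3 (-1.17, 0.0231). With the set it was -0.54 (0.0245, and adjusted p = 0.778 with an estimated correlation).

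At 3 days after surgery, 5 genes rose, 4 of them on the immediate early list, and 1 gene fell. Fos, a transcription factor of activated neurons on chromosome 12 from 85473890 to 85477273, reached 46.9 ± 2.37 CPM (SD, n = 3) against 17.5 ± 2.70 CPM (n = 4) in controls. Its log2 fold change was 1.43 ± 0.22 (SE). Arc, a synaptic plasticity gene on chromosome 15 from 74669083 to 74672570, rose by 1.32 ± 0.21 to 443 ± 75.2 CPM. Junb rose by 1.04 ± 0.16, the feedback inhibitor gene Errfi1 by 0.59 ± 0.09 (these 4 at adjusted p = 0.0425) and the clock gene Per1 by 0.55 ± 0.09 (0.0478). Gbp7, an interferon-induced GTPase gene on chromosome 3 from 142530342 to 142550149 that overlaps another gene model on its strand, fell by 1.70 ± 0.27 to 1.60 ± 0.266 CPM (adjusted p = 0.0425). Lower and not passing were Drp2 at -0.77 ± 0.13 (0.062), the pericyte gene Cd248 at -0.92 ± 0.18 (0.154) and Ccdc171 at -0.87 ± 0.18 (0.162). By edgeR, 2131 genes had an unadjusted p below 0.05, and DESeq2 called 54 and voom 311. When the set was a term, Fos, Junb, Errfi1, Gbp7 and Per1 had an adjusted p of 0.119 and Arc of 0.212, and the 1 gene called was Per2 (0.72, 0.0175), named after its values were seen. Within the shallower set 11 genes passed, Fos among them at 1.28 (0.00931). The count was 0 without CON 1 (1186 genes at an unadjusted p below 0.05) or CON 2 (1096), 1 without 3D 1 or 3D 3, 3 without 3D 4, 15 without CON 4 and 16 without CON 5. None of the 6 genes passed without CON 1 (lowest adjusted p = 0.179), CON 2 (0.122), 3D 1 (0.266) or 3D 3 (0.191). Without 3D 4 Errfi1 and Per1 kept their call (0.0146), and Arc (0.0577), Fos (0.0788), Junb (0.113) and Gbp7 (0.147) did not. Without CON 5 Arc and Per1 were at 0.0576.

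Immediate early genes at 3D had a median of 0.68 with 23 of 25 members higher, 4 called over all genes and 22 when adjusted over the list alone. Camera gave an adjusted p = 1.69e-22, and adjusted p = 0.192 with an estimated correlation. The median was 0.64 with the set and 0.61 within the shallower set. Chaperone genes such as Dnajb1 at 0.68 ± 0.16 (SE, n = 3 and 4), Sdf2l1 at 0.97 and Hspa1b at 1.14 were higher in 23 of 28 members, 5 when adjusted over the list alone. Their median was 0.28 (adjusted p = 4.12e-07, and adjusted p = 0.538 with an estimated correlation) and 0.25 with the set. Glucocorticoid targets such as Tsc22d3 at 0.67 and the kinase gene Sgk1 at 0.88 ± 0.24 were higher in 22 of 25. Of these 1 was called and 4 passed when adjusted over the list alone. Their median of 0.32 (adjusted p = 6.24e-06, and adjusted p = 0.538 with an estimated correlation) was 0.13 with the set. Clock genes were higher in 14 of 19 (median 0.10, adjusted p = 0.0141, and adjusted p = 0.313 with an estimated correlation), with Per2 at 0.57 ± 0.11 and Cry2 at 0.19. Their median was 0.17 with the set, 0.16 without CON 1, 0.040 without CON 4, 0.064 without CON 5 or 3D 1, and 0.095 with voom, where the list was not called (0.0578). Of the clock genes 1 was called, Per1, and 3 passed when adjusted over the list alone. Per1 is on the immediate early list too, among its 4 called members.

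Interferon-induced genes at 3D were lower in 23 of 24 members (median -0.28, adjusted p = 0.000225, and adjusted p = 0.574 with an estimated correlation). Gbp3 at -1.01 ± 0.30 (SE, n = 3 and 4), Trim30a at -0.58 and Cmpk2 at -0.28 were examples, and the median with the set was -0.26. Fibroblast genes of the leptomeninges, the membranes around the brain, were lower in 19 of 20 (median -1.03, adjusted p = 2.03e-07, and adjusted p = 0.538 with an estimated correlation), 12 of them when adjusted over the list alone. Aox3 at -1.60 ± 0.37, Slc6a20a at -1.08 and Islr at -0.45 were among them, and with the set the median was -0.27. It was -0.16 (0.043) within the shallower set, and -0.16 (0.118) and not called without the libraries of high choroid plexus score. Choroid plexus genes such as Trpv4 at -1.85, Slc13a4 at -2.23 and Col8a1 at -3.16 were lower in 28 of 29. Their median of -1.77 (adjusted p = 0.00052, and adjusted p = 0.726 with an estimated correlation) became 0.10 (0.71) with the set and 0.20 within the shallower set, and was -0.85 (0.186) without CON 2.

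At 7 days after surgery edgeR called 0 genes, with 1914 at an unadjusted p below 0.05, against 74 called by DESeq2 and 1 by voom. Higher and not passing were the imprinted gene Peg10 at 1.05 ± 0.18 (SE, n = 3 and 4; adjusted p = 0.151), Sik1 at 0.83 ± 0.15 and Fos at 1.17 ± 0.22. Lower and not passing were Drp2 at -0.93 ± 0.13 (0.0559), the myelin-related Tmem98 at -0.91 ± 0.17 and the ion pump regulator Fxyd1 at -0.65 ± 0.12 (0.191). Adding the set as a term, 4 genes passed, named after their values were seen: Drp2 at -1.02 (0.0214), Prr32, Prkar2b and Pon3. Within the deeper set 13 genes passed, Drp2 among them at an adjusted p of 0.028. The count was 1 without CON 5 and 1 without 7D 3. It was 1965 with the choroid plexus score as a covariate and 3098 without the 6 libraries of high score, fits that leave the set out.

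Immediate early genes at 7D had a median of 0.45 with 23 of 25 higher (adjusted p = 1.53e-09, and adjusted p = 0.538 with an estimated correlation). When adjusted over the list alone 9 were higher, Per1 at 0.45 among them, and 1 was lower, Ier3 at -0.74, named after its value was seen. The median was 0.58 with the set and 0.74 within the deeper set. It was 0.28 with the choroid plexus score as a covariate, 0.43 with set and score, and 0.19 (0.115) and not called without the libraries of high score. The last fit sets deeper 7D libraries against shallower controls. Chaperone genes, with the endoplasmic reticulum gene Hspa5 at 0.91 ± 0.23 (SE, n = 3 and 4) and the mitochondrial gene Hspd1 at 0.32, were higher in 21 of 28. Their median of 0.24 (adjusted p = 0.000883, and adjusted p = 0.618 with an estimated correlation) was 0.19 with the set. The chaperone list was not called without CON 2 (0.19, 0.0721) or 7D 3 (0.14, 0.0823). Nor was it with the choroid plexus score as a covariate (0.248), with set and score (0.657) or without the libraries of high score (0.548). Choroid plexus genes were lower in 29 of 29, 24 of them when adjusted over the list alone, with Kcne2 at -4.82 ± 1.51, Trpv4 at -2.15 ± 0.60 and Slc29a4 at -0.37. Their median of -2.23 (adjusted p = 5.76e-10, and adjusted p = 0.538 with an estimated correlation) was -1.27 without CON 2 and -3.05 with the set, under which all 29 passed when adjusted over the list alone.

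Myelin genes at 7D were lower in 20 of 20 members, 13 of them when adjusted over the list alone, with Mog at -0.64 ± 0.17 (SE, n = 3 and 4), Mbp at -0.59 and Opalin at -0.99. Their median was -0.56 (adjusted p = 2.08e-09, and adjusted p = 0.538 with an estimated correlation) and -0.32 with the set. It was -0.20 within the deeper set, and -0.15 (0.0501) and not called with set and score. Genes of the microglial state seen around damage, such as Trem2 at -0.78 ± 0.22, Cd9 at -0.52 and the lysosomal Cd63 at -0.39, were lower in 21 of 22. Of these, 5 passed when adjusted over the list alone, and the median of -0.39 (adjusted p = 2.03e-07, and adjusted p = 0.538 with an estimated correlation) was -0.18 with the set, -0.12 (0.015) within the deeper set and -0.25 without CON 5. With set and score it was 0.0039 (0.817). Interferon-induced genes were lower in 18 of 24 (median -0.23, adjusted p = 0.00762, and adjusted p = 0.663 with an estimated correlation), with Ifi27l2a at -2.32 ± 0.53, Bst2 at -0.98 and Ifitm3 at -0.57. Without 7D 2 the interferon median was 0.01 (0.807), without CON 5 it was -0.11, and with the set it was -0.24. It was -0.11 within the deeper set, and not called with the score as a covariate (0.454), with set and score (0.691) or without the libraries of high score (0.106). Red cell genes such as Alas2 at -4.80 ± 1.37, Hba-a1 at -3.70 ± 1.12 and Bpgm at -0.31 were lower in 7 of 8, 6 of them when adjusted over the list alone. Their median of -3.64 (adjusted p = 0.00121, and adjusted p = 0.538 with an estimated correlation) was -0.84 (0.0773) with the set and -0.03 within the deeper set.

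At 1 month after surgery 47 genes were called, 39 higher and 8 lower, with 2779 at an unadjusted p below 0.05. Activity-induced genes led the risen ones. Fos rose by 1.89 ± 0.21 (SE) to 64.4 ± 21.5 CPM (SD, n = 4), Arc by 1.74 ± 0.20 to 591 ± 119 CPM and Junb by 1.21 ± 0.16 to 140 CPM (adjusted p = 0.00271). Per1, on chromosome 11 from 69095217 to 69109960, rose by 0.72 ± 0.08 from 91.2 ± 3.82 to 150 ± 8.48 CPM. Sik1 rose by 1.22 ± 0.14 (0.0012), the nuclear receptor gene Nr4a1 by 1.31 ± 0.19 (0.00877), the phosphatase gene Dusp6 by 0.59 ± 0.09 (0.0128) and the heat shock gene Hspa1l by 1.90 ± 0.28. These 8 still passed with the set as a term, with adjusted p from 0.00736 for Fos and Per1 to 0.0473 for Hspa1l. Of the same 8, Dusp6 was lost without CON 1 (0.0572) or 1M 4 (0.0508), and the other 7 kept their call without any 1 of the 8 libraries. Within the shallower set, 4 libraries against 2, Per1 alone of the 8 passed, at 0.68 (0.0202). Fos was at 1.73, Sik1 at 1.08, Junb at 0.96 and Dusp6 at 0.41 (all 0.107), Arc at 1.53 (0.0773), and Hspa1l at 1.75 and Nr4a1 at 0.97 (both 0.239).

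Of the genes that fell at 1M, Drp2 was lowest in p, at -0.91 ± 0.12 (SE, n = 4 and 4; adjusted p = 0.00426) and 48.6 ± 6.48 CPM. It was at -0.81 (0.021) with the set and -0.84 (0.107) within the shallower set. The tRNA synthetase gene Lars fell by 0.45 ± 0.07 (0.0132), the nuclear matrix gene Matr3 by 0.87 ± 0.15 (0.0183) and Zfp330 by 0.51 ± 0.09 (0.0256). Gbp7 fell by 1.19 ± 0.23, the lipase gene Lpl by 0.66 ± 0.13 (0.0442), the zinc finger gene Zfp937 by 0.84 ± 0.16 and the DNA sensor gene Aim2 by 0.74 ± 0.15. With the set as a term Lars and Matr3 were at an adjusted p of 0.0473, and Zfp330 (0.0842), Lpl (0.0956), Aim2 (0.12), Zfp937 (0.133) and Gbp7 (0.138) no longer passed. Drp2 kept its call without any 1 of the 8 libraries. Lars lost it without CON 1 (0.0572) or 1M 4 (0.0508), and Aim2 without each library, with adjusted p from 0.0534 without CON 5 to 0.150 without CON 2. Matr3 and Zfp330 lost theirs without CON 1 (0.0697 and 0.0961), CON 2 (0.0796 and 0.107), 1M 3 (0.072 and 0.0905) or 1M 4 (0.085 and 0.0887). Gbp7 lost its call without CON 1 (0.151), CON 2 (0.142), CON 4 (0.0594), 1M 2 (0.120), 1M 3 (0.086) or 1M 4 (0.128). Lpl lost it without CON 1 (0.152), CON 2 (0.157), 1M 2 (0.117), 1M 3 (0.144) or 1M 4 (0.133). Zfp937 lost it without CON 1 (0.145), CON 2 (0.158), CON 4 (0.0739), 1M 1 (0.0832), 1M 2 (0.099), 1M 3 (0.0678) or 1M 4 (0.144).

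At 1M the count of called genes was 22 with the set as a term, 18 higher and 4 lower, of which 14 were among the 47. It was 10 within the shallower set, of which 2 were among the 47, 391 by DESeq2 and 2014 by voom. It was 10 without CON 1, 12 without CON 2, 129 without CON 5, 18 without 1M 2, 14 without 1M 3 and 8 without 1M 4. Among other called genes were Dnajb1 of the chaperone list at 0.87 ± 0.15 (SE) and Per2 of the clock list at 0.57 ± 0.10. Both lists were chosen for description after their values were seen. Dnajb1 lost its call with the set (0.0598) and without CON 1 (0.0697), CON 2 (0.091), 1M 2 (0.0597), 1M 4 (0.0616) or 1M 3. Per2 kept it with the set, at 0.72 (0.00736), and lost it without CON 2 (0.0813), CON 4 (0.0594), 1M 2 (0.095), 1M 3 (0.099) or 1M 4 (0.0508).

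Immediate early genes at 1M had a median of 0.89 with 24 of 25 higher, 13 called and 23 when adjusted over the list alone. Camera gave an adjusted p = 4.95e-26, and adjusted p = 0.192 with an estimated correlation. The median was 0.80 with the set and 0.77 within the shallower set. Chaperone genes, with the inducible Hspa1b at 1.75 ± 0.33 (SE, n = 4 and 4) and Hspa1a at 1.57 ± 0.31, were higher in 25 of 28, 3 called and 12 when adjusted over the list alone. Their median of 0.30 (adjusted p = 1.09e-08, and adjusted p = 0.538 with an estimated correlation) was 0.29 with the set. Hspa1b lost its call with the set (0.103) and without CON 1 (0.116), CON 2 (0.144), 1M 2 (0.0906), 1M 3 (0.0678), 1M 4 (0.0711) or CON 4. Hspa1a lost it with the set (0.115) and without CON 1 (0.145), CON 2 (0.158), CON 4 (0.0739), 1M 2 (0.109), 1M 3 (0.0678) or 1M 4 (0.0925). Glucocorticoid targets, with Errfi1 at 0.50, Tsc22d3 at 0.66 and Arl4d at 1.13, were higher in 20 of 25, 1 called and 6 when adjusted over the list alone. Their median of 0.33 (adjusted p = 2.2e-05, and adjusted p = 0.538 with an estimated correlation) was 0.13 with the set, 0.033 (0.146) with set and score, and 0.05 (0.324) without the libraries of high choroid plexus score. Errfi1, the called one, lost its call with the set (0.0513) and without CON 1 (0.0697), CON 2 (0.0796), 1M 2 (0.0603), 1M 3 (0.060) or 1M 4 (0.0508). Clock genes, with Per1 of the immediate early list, were higher in 13 of 19, 2 called and 5 when adjusted over the list alone. Their median was 0.13 (adjusted p = 0.00244, and adjusted p = 0.192 with an estimated correlation), 0.13 with the set and 0.084 without 1M 1, and Cry1, at 0.55 ± 0.12 (0.0755), passed with the set at 0.74 (0.0136).

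Leptomeningeal genes at 1M were lower in 18 of 20, 2 of them when adjusted over the list alone, with Aox3 at -1.12 ± 0.32 (SE, n = 4 and 4), Slc6a20a at -0.96 and Col1a1 at -0.67. Their median of -0.82 (adjusted p = 0.000972, and adjusted p = 0.646 with an estimated correlation) was 0.01 (0.873) with the set and -0.47 (0.0631) without CON 1. Choroid plexus genes, 28 of 29 lower, were not called (median -0.69, adjusted p = 0.24), with Slc13a4 at -1.36, Enpp2 at -0.96 and Col8a1 at -1.25. With the set their median was 1.26 (0.000578, and adjusted p = 0.645 with an estimated correlation), and 1.53 within the shallower set. Without CON 2 it was 0.21 (0.298), and it passed in the lower direction without CON 4 (-1.04, 0.00948), CON 5 (-1.02, 0.0146), 1M 1 (-1.56, 0.0084) or 1M 3 (-0.76, 0.048). Myelin genes were lower in 16 of 20 and not called (median -0.11, adjusted p = 0.189), with Aspa at -0.36 ± 0.15 and Opalin at -0.51 ± 0.26. With the set their median was -0.29 (1.77e-05, and adjusted p = 0.554 with an estimated correlation), and within the shallower set -0.38 (1.09e-09). Without CON 1 the myelin list passed at 0.00346, without CON 2 at 0.00488 and without 1M 1 at 0.0416.

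**Figure D3:**
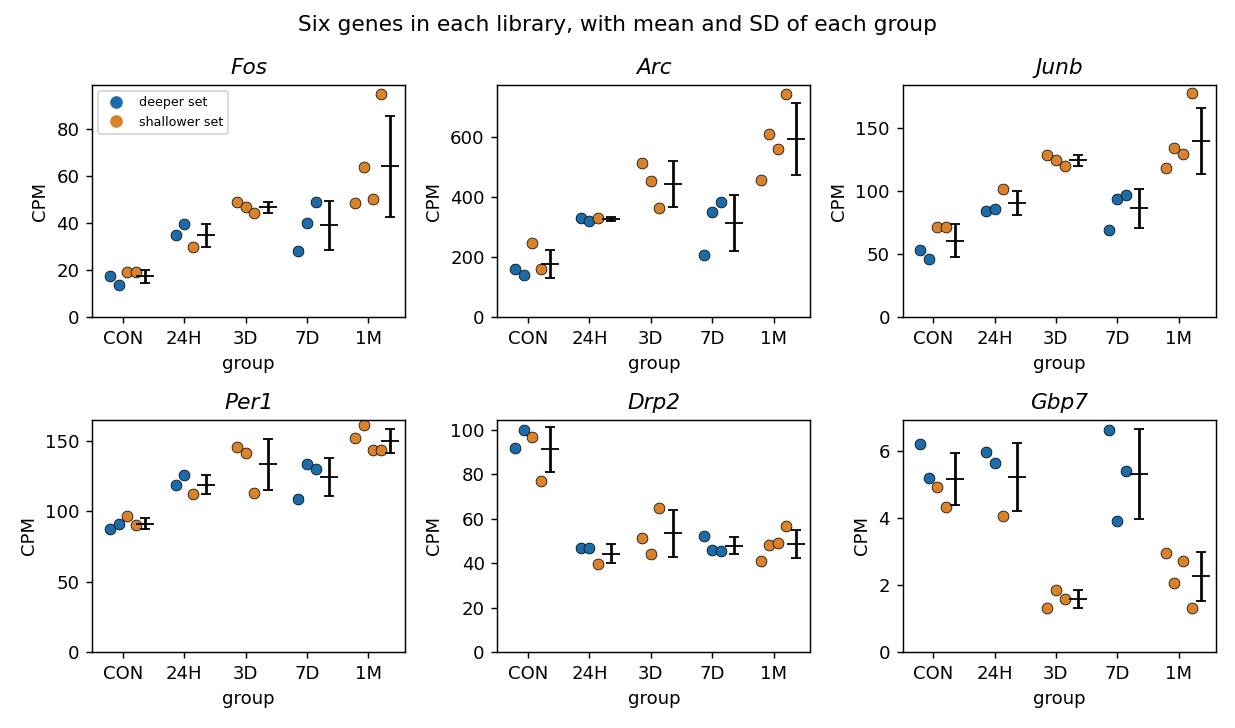
CPM of Fos, Arc, Junb, Per1, Drp2 and Gbp7 in each of the 17 libraries by group, with the group mean and SD. All 13 operated libraries lie above the highest control for Fos and below the lowest control for Drp2. Both genes were picked for their low p in these libraries, so the separation is not a further test.

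**Figure D4:**
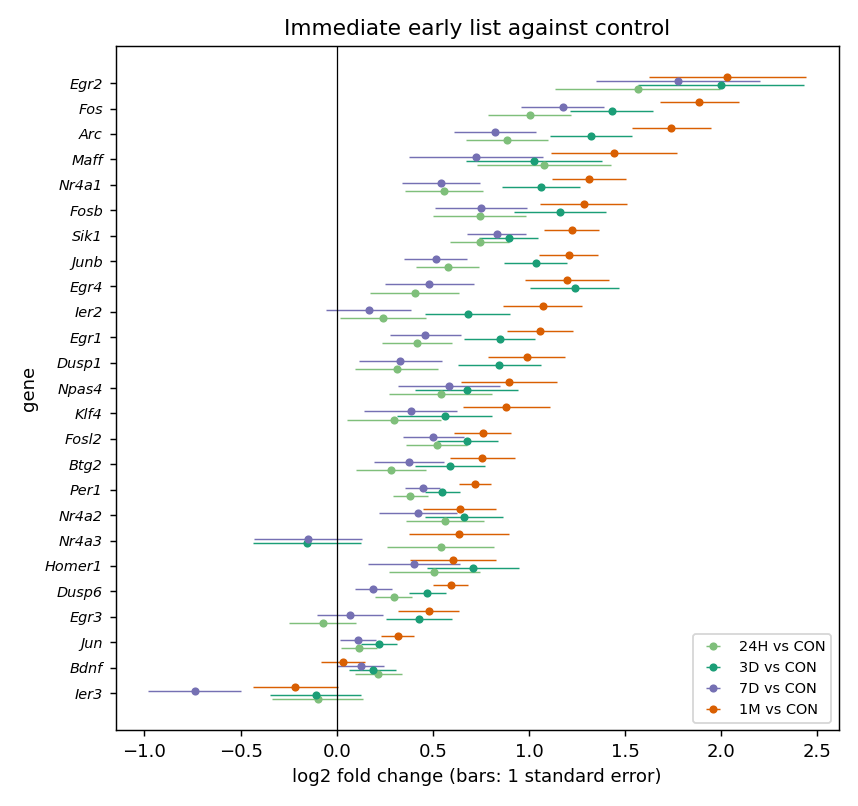
Log2 fold change against control with 1 SE for the 25 immediate early genes in the 4 comparisons, without the set as a term. Between 23 and 24 of the 25 lie above 0 at each time.

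Across the 5 groups together, 15 genes were called by edgeR, with 4403 at an unadjusted p below 0.05, and 8 with the set as a term. The lowest p was that of Drp2 (F = 24.6, adjusted p = 0.0199; 0.0152 with the set). Fos followed (F = 21.6, adjusted p = 0.0217; 0.0481 with the set), with Arc, Per1, Sik1, Gbp7, Junb, Matr3 and Tsga10 at the same adjusted p and the galectin gene Lgals8 at 0.0248. With the set, Per1 and Junb were at 0.0481 and Sik1 at 0.0488, and Arc was at 0.0725, Matr3 at 0.233, Gbp7 at 0.234, Lgals8 at 0.252 and Tsga10 at 0.309. Fos was at most 19.5 CPM in controls and at least 28.4 CPM in operated libraries of 7D, and Drp2 was at least 76.9 CPM in controls and at most 65.0 CPM in those of 3D. DESeq2 called 2941 genes and voom 3823. The count was 0 without CON 1 (4321 genes at an unadjusted p below 0.05) or 1M 2 (4023), 29 without CON 2, 391 without CON 4, 1057 without CON 5 and 3100 without 24H 4. It was 5 without 3D 1, 8 without 7D 1 or 7D 2, and 7 without 7D 3, 1M 1 or 1M 3.

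All 5 genes that rose at 3D (Arc, Errfi1, Fos, Junb and Per1) were among the 39 that rose at 1M. Gbp7 fell at both times, and Drp2 at 24H and 1M. With the set the 1 gene that rose at both 3D and 1M was Per2, and Drp2 fell at 24H, 7D and 1M. These comparisons share the same controls, which alone gives related fold changes. The set difference relates them as well, since 3D and 1M both lie in the shallower set and 7D in the deeper. Across genes, which are not independent replicates, log2 fold changes at 3D and 1M correlated at r = 0.656. In simulated data without effects of surgery, which kept both the shared controls and the set difference, r was 0.685. With the controls divided 2 and 2 between the comparisons r was 0.395. With the set as a term these were 0.592, 0.573 and 0.318. Without the set r was 0.245 for 24H and 3D, 0.596 for 24H and 7D, 0.321 for 24H and 1M, 0.197 for 3D and 7D, and 0.175 for 7D and 1M. In simulated data these 5 were 0.145, 0.488, 0.152, -0.137 and -0.142, and with divided controls 0.0148, 0.296, 0.0639, 0.00896 and -0.0183. In the same order r with the set was 0.341, 0.560, 0.359, 0.188 and 0.0803, against 0.281, 0.465, 0.299, 0.126 and 0.140 in simulated data. For 7D and 1M it was thus below the value without effects. With the set and divided controls r was 0.0708, 0.264, 0.1001, -0.00806 and -0.0848.

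Between 24H and 3D edgeR called 0 genes, with 3330 at an unadjusted p below 0.05, against 243 called by DESeq2 and 2716 by voom. Of lowest p and not passing (adjusted p = 0.168) were the neurogenic factor gene Neurog2 at 1.32 ± 0.29 (SE, n = 3 and 3), Adck3 at 0.90 ± 0.19, Mrps24 at 0.67 ± 0.14, Gbp7 at -1.72 ± 0.28, Manea at -0.56 ± 0.10 and the cohesin gene Smc1a at -0.48 ± 0.09. Adding the set gave Neurog2 1.28, Adck3 0.89, Mrps24 0.41, Gbp7 -1.45, Manea -0.41 and Smc1a -0.29, all at adjusted p = 0.627. Ttr was at -2.78 without the set and 1.44 (0.904) with it. The count with the set as a term was 0 by edgeR, with 1034 at an unadjusted p below 0.05. Without 24H 4, the 1 library of 24H in the shallower set, it was 2471. It was 1 without 24H 2 or 3D 3 and 2 without 3D 1. Within the shallower set, with 1 library of 24H, it was 23.

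Between 3D and 7D 1107 genes were called, 533 higher and 574 lower, and this comparison sets the 3 shallower libraries of 3D against the 3 deeper ones of 7D. With the set as a term edgeR called 0 genes, with 883 at an unadjusted p below 0.05, and no other tool was run with that term. Gbp7 rose by 1.74 ± 0.28 (SE, n = 3 and 3), the spermatogenesis gene Tsga10 by 0.63 ± 0.10, the mitochondrial translation gene Ptcd3 by 0.62 ± 0.10 and Lgals8 by 0.49 ± 0.08, all at adjusted p = 0.0412. At the same adjusted p the claudin gene Cldn22 fell by 1.43 ± 0.22, the receptor gene Gpr19 by 1.32 ± 0.23, and the ribosomal protein genes Rpl26 by 1.08 ± 0.20 and Rps21 by 0.97 ± 0.18. None of these 8 passed with the set, where Gbp7 was at 1.36, Tsga10 at 0.39, Ptcd3 at 0.31, Lgals8 at 0.46, Cldn22 at -1.08, Gpr19 at -0.84, Rpl26 at -0.50 and Rps21 at -0.43. Leaving out any 1 of the 6 libraries ended nearly all calls, with 1 left without 3D 1, 2 without 3D 3 and 0 without 3D 4 (4155 at an unadjusted p below 0.05). There was 1 left without 7D 1, 0 without 7D 2 (4235) and 4 without 7D 3. Ttr was at -2.09 ± 1.61 (0.389), and at -6.96 ± 1.74 (0.569) with the set.

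Between 7D and 1M 2451 genes were called, 1150 higher and 1301 lower, again across the sets, and with the set as a term 0, with 1123 at an unadjusted p below 0.05 by edgeR. Fxyd1 rose by 0.84 ± 0.12 (SE, n = 4 and 3), the calcium-binding gene S100a1 by 0.75 ± 0.12, Fbxl14 by 0.59 ± 0.09 and the ATP synthase gene Atp5g1 by 0.58 ± 0.09, all at adjusted p = 0.0193. Matr3 fell by 1.13 ± 0.16, Tsga10 by 0.64 ± 0.10, the splicing gene Srsf12 by 0.63 ± 0.10 and Ptcd3 by 0.61 ± 0.10 at the same adjusted p. None of these 8 passed with the set, where Fxyd1 was at 0.62, S100a1 at 0.37, Fbxl14 at 0.34, Atp5g1 at 0.36, Matr3 at -0.66, Tsga10 at -0.40, Srsf12 at -0.36 and Ptcd3 at -0.31. The count was 0 without 7D 1 (4369 at an unadjusted p below 0.05), 7D 2 (4637) or 1M 3 (4753), 6 without 1M 4, 433 without 7D 3 and 1558 without 1M 1. Ttr was at 4.59 ± 1.74 (0.0783), and at 9.46 ± 1.83 (0.0836) with the set. In both comparisons the set is separated from the time only through the control and 24H libraries, which both sets hold.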

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

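The tests of Ttr and of surgery as a cause of the library sets, the library set as a cause of the Ttr pattern, and all set-based values here were chosen only after the result was seen. The same holds for splits as unbalanced by set as the real one, while thinning, GC content, transcript length and the splits at large were planned.

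Of 127 groups of 4 libraries tested for a library far from the rest, 5 had a gap above the limit, and chance alone gives about 1 in 20. The gap over the range was 0.872 for Bst2 in CON 1, at a log2 CPM of 1.75 against 2.58 to 2.70 in the other controls. It was 0.888 for Ifi27l2a in CON 5, at 0.98 against 0.13 to 0.23. It was 0.845 for Tsc22d3 in CON 5, at 6.35 against 5.62 to 5.74, and 0.832 for Vangl2 in CON 5, at 3.81 against 3.97 to 4.00. It was 0.849 for Zfp330 in CON 4, at 4.03 against 4.33 to 4.38.

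The change against control differed between 3D and 7D for 1107 genes by edgeR, and for 0 with the library set as a term, with 883 at an unadjusted p below 0.05. Among genes that the naming rule took for 3D or 7D against control, 4 were called higher at 7D than at 3D. They were Aox3 by 1.48 on the log2 scale, Ccdc171 by 1.04, Gbp7 by 1.74 and Peg10 by 0.69. Of the same genes, those called lower at 7D than at 3D were Errfi1 at -0.34, Fxyd1 at -0.63, Mbp at -0.88, Mog at -0.72, Slc29a4 at -0.46, Tmem98 at -0.69 and Trem2 at -0.94. The adjusted p of these 11 ran from 0.0412 for Gbp7 to 0.0457 for Errfi1. With the set as a term none passed: Aox3 was at 0.35, Ccdc171 at 0.79, Gbp7 at 1.36, Peg10 at 0.48, Errfi1 at -0.32, Fxyd1 at -0.41, Mbp at -0.42, Mog at -0.41, Slc29a4 at -0.31, Tmem98 at -0.51 and Trem2 at -0.20.

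The change against control differed between 7D and 1M for 2451 genes by edgeR, and for 0 with the library set as a term, with 1123 at an unadjusted p below 0.05. The genes that follow are those that the naming rule took for 7D or 1M against control. Higher at 1M than at 7D were the red cell genes Alas2 by 5.03 on the log2 scale and Hba-a1 by 3.71. Also higher were the interferon-induced Bst2 by 1.11, Ifi27l2a by 2.15 and Ifitm3 by 0.64, and the microglial Trem2 by 0.99, Cd63 by 0.44 and Cd9 by 0.43. The same held for the immediate early genes Fos by 0.71, Arc by 0.92, Junb by 0.69, Nr4a1 by 0.77 and Dusp6 by 0.40, and the heat shock genes Hspa1b by 1.08 and Hspa1l by 1.17. Fxyd1 was higher by 0.84, Mbp by 0.70, Slc29a4 by 0.44 and Tmem98 by 0.70. Lower at 1M than at 7D were Hspd1 at -0.38, Peg10 at -0.64, Aim2 at -0.59, Gbp7 at -1.22, Lars at -0.45, Lpl at -0.53, Matr3 at -1.13, Zfp330 at -0.49 and Zfp937 at -1.04. None of these passed with the set. The red cell genes were then at 1.96 for Alas2 and 0.34 for Hba-a1, Bst2 was at 0.98, Ifi27l2a at 1.88 and Ifitm3 at 0.42, and Trem2 at 0.25, Cd63 at 0.34 and Cd9 at 0.28. Fos was at 0.65, Arc at 0.65, Junb at 0.27, Nr4a1 at 0.20, Dusp6 at 0.19, Hspa1b at 1.01 and Hspa1l at 1.06. Fxyd1 was at 0.62, Mbp at 0.24, Slc29a4 at 0.29 and Tmem98 at 0.52. Hspd1 was at -0.04, Peg10 at -0.43, Aim2 at -0.43, Gbp7 at -0.84, Lars at -0.37, Lpl at -0.10, Matr3 at -0.66, Zfp330 at -0.44 and Zfp937 at -0.82.

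The first pattern weighed is the set of libraries, between which 4830 genes differed. Depth alone and surgery are argued against as whole causes: after every library was thinned to 1.52e+07 counts 4518 genes differed (93.5% as many), and 3278 genes differed between control libraries of the 2 sets. A difference in GC content is consistent with the data, since across genes, which are not independent replicates, GC content and the set difference had a Spearman rho of 0.391. Transcript length had a rho of -0.200 and stays open. The labels name no batch, so a separate preparation, collection or sequencing of the 2 sets, or a difference in tissue or RNA quality, also stays open as untested.

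The second pattern is the spread of Ttr between libraries and groups, for which choroid plexus tissue carried into some libraries is a candidate explanation. Ttr followed the score of the other choroid plexus genes, which formed 2 clusters, with a Pearson r of 0.963 over the 11 libraries of low score (permutation p = 1e-05, the smallest these permutations can give, adjusted 3e-05; Spearman rho 0.918, permutation p = 0.00028; r 0.929 without the 2 libraries farthest from the median). Over the 6 of high score r was 0.984 (exact permutation p = 0.00278, adjusted 0.00417; rho 0.943, exact permutation p = 0.0167; r 0.975 without 2), and over the 8 of low score in the shallower set 0.890 (exact permutation p = 0.00494; rho 0.881, exact permutation p = 0.00724; r 0.893 without 2), 3 relations in all, two-sided. The library set is argued against as the whole cause by 2 libraries of the shallower set with a score above 2, beside 4 of the deeper set, and a change of Ttr apart from the other choroid plexus genes stays open, with a joint p of 0.489 from edgeR with set and score as terms and log2 fold changes from -0.20 ± 0.51 (SE) at 1M to 0.53 ± 0.48 at 3D. A coordinated change of choroid plexus tissue after surgery, with all 3 libraries of 7D low, was not told from dissection by any test here and stays open.

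Other splits of the libraries gave the following counts of called genes. At 24H, 8 of 35 splits gave at least the real count of 1, so chance cannot be excluded, and the highest other, 4936, parted the libraries by set, which points to that structure of the samples. At 3D, 2 of 35 splits gave at least the real 6, with 7 as the highest other, so chance cannot be excluded. At 7D, 35 of 35 splits gave at least the real 0, with 112 as the highest other. At 1M, 1 of 35 splits, the real one, gave 47, with 21 as the highest other. This share is under 0.05 and the smallest that these splits can give. They ignore the library set, which the controls mix and 1M does not, so chance is not excluded. Of the 15 splits as unbalanced by set as the real one, 1 gave 47, which are too few for a share under 0.05, and with the set as a term 22 genes were called. Of such splits, 1 of 18 at 24H and 1 of 10 at 3D gave at least the real count, also too few. For 1M against 7D, 1 of 35 splits gave the real 2451, with 2 as the highest other, and the real split follows the library sets, with 0 called when the set is a term. For the joint test 3 of 100 splits, drawn at random apart from the real one, gave at least the real 15, with 1764 as the highest other. What the split with 1764 parts was not examined. For 3D against 24H (real 0, highest other 1) and 7D against 3D (real 1107, highest other 1) the 10 splits are too few for a share under 0.05.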

How the results depend on the processing

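Alternatives that use the library set, or leave out the libraries of high choroid plexus score, were chosen only after the data were seen, and the others before. No cause of a changed value below was tested, except that alternatives with fewer libraries hold less information. For the 131 results of genes taken by the naming rule, 2143 of 2624 alternative values kept direction and side of the threshold, 334 kept the direction and lost the call, 137 gained a call and 10 changed direction. Many of the 131 were not called and kept their side by staying uncalled. Only called results can lose a call, so 334 of 2624 understates the share lost among called genes. For the 28 list results, 499 of 562 values kept both, 29 lost a call, 20 gained one and 14 changed direction. Of 173 alternative counts of called genes 60 stayed within 1.5 times the reported count. Counts follow in the order 24H, 3D, 7D and 1M against control, 3D against 24H, 7D against 3D, 1M against 7D, and joint. Reported were 1, 6, 0, 47, 0, 1107, 2451 and 15. RLE size factors gave 1, 6, 0, 50, 0, 1097, 2428 and 15, library totals 1, 5, 0, 43, 0, 1278, 2561 and 61, no filter 1, 6, 0, 47, 0, 992, 2368 and 15, and the stricter filter 1, 6, 1, 60, 0, 1378, 2679 and 139. DESeq2 gave 12, 54, 74, 391, 243, 2760, 3551 and 2941, and voom 5, 311, 1, 2014, 2716, 4223, 4885 and 3823. The compared groups alone gave 0, 2, 2, 9, 1, 3684 and 4343. The choroid plexus score as a covariate gave 1, 0, 1965, 82, 0, 4557, 5645 and 3795, the set as a term 1, 1, 4, 22, 0, 0, 0 and 8, both 1, 1, 0, 14, 0, 0, 0 and 5, and leaving out the 6 libraries of high score 11, 2, 3098, 14, 10, 3937, 3176 and 2672. The deeper set alone gave 7 at 24H and 13 at 7D, and the shallower 38, 11 and 10 at 24H, 3D and 1M and 23 for 3D against 24H, where 1 library of 24H is assumed to vary as the others. A log2 fold change of 1 as well left 1, 4, 0, 17, 0, 146 and 183. The replicate number as a block gave 0, 11, 1, 850, 0, 0, 2306 and 1303, a choroid plexus median of -0.75 at 24H and -1.08 at 1M, and nothing in the labels makes the numbers a pairing. Residual correlation between libraries of a number was 0.14 and 0.36 for the 2 numbers that 24H and controls share. In the other comparisons it ran from -0.12 to 0.074. The libraries of each of those 2 pairs share a set, which was not removed, so their values cannot tell pairing from the set. Counts of 0 are from edgeR, with the counts at an unadjusted p below 0.05 of the reported ones in the report. Without each library in turn the counts ran from 0 to 6, 0 to 16, 0 to 1, 8 to 129, 0 to 2471, 0 to 4, 0 to 1684 and 0 to 3100. Without 24H 4 the joint count was 3100 and that of 3D against 24H 2471, and without CON 5 the 1M count was 129.

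Ttr changed direction at 24H with voom (0.052), the score (0.070) and set and score (0.18), and ran from -1.59 without 24H 3 to 0.83 without CON 2. At 3D it was 0.64 with the score, 0.78 with the set, 0.89 in the shallower set and 0.53 with both terms. At 7D DESeq2 called it at -5.34 (adjusted p = 0.0446, against 0.347 by edgeR). At 1M it was 0.018 with the score, 3.28 with the set and 3.38 in the shallower set, and ran from -2.005 without 1M 1 to 0.55 without CON 2. Without the libraries of high score the immediate early median at 24H was 0.20 and the chaperone median -0.041, with 24H 4 alone against CON 4 and CON 5. In the shallower set the chaperone median at 24H was -0.037. At 7D the immediate early median without the libraries of high score was 0.19 and not called, with deeper 7D libraries against shallower controls. The choroid plexus median at 24H was -0.54 with the set and -0.79 in the deeper set, now called, and ran from -1.17 without 24H 3 to 0.68 without CON 2. At 3D it was 0.10 with the set and 0.20 in the shallower set, and ran from -2.10 without CON 4 to -0.85 without CON 2. At 1M it was -0.67 with DESeq2 and -0.995 with voom, now called, 1.26 with the set and 1.53 in the shallower set, and ran from -1.56 without 1M 1 to 0.21 without CON 2. The leptomeningeal median at 1M was 0.012 with the set, 0.11 in the shallower set and 0.16 without the libraries of high score, and the myelin median was 0.047 with voom. At 7D the median of damage-associated microglial genes was 0.0039 with set and score, and the interferon median ran from -0.32 without 7D 3 to 0.0076 without 7D 2. Bst2 at 7D was 0.29 with set and score. Col8a1 at 1M was 1.59 with the set, 1.71 in the shallower set and 0.51 with set and score, Enpp2 was 0.64 and 0.68 and Slc13a4 0.56 and 0.65 with the set and in the shallower set. Without 24H 3 Aqp1 at 24H was -1.94 and Car12 -0.41, and without CON 2 they were 0.23 and 0.062. With 1.52e+07 to 2.94e+07 counts per library, depth limits genes near 1 CPM most.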

Other observations

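The tests of the library set, neuron share and clock phase, and the choice of which lists to describe, were chosen only after the result was seen.

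Inflammatory cytokine and NF-kB target genes as a list were called at no time (adjusted p = 0.947 at 24H, 0.733 at 3D, 0.868 at 7D and 0.194 at 1M), and the table lists no gene that was off in more than 1 library. Of the 30 members fixed for this list 21 were tested. Il1b, Il6 and Tnf are among those not tested, so the result does not cover them. Complement and antigen presentation genes were lower at 7D in 16 of 19 members (median log2 fold change -0.38, adjusted p = 0.000753, and adjusted p = 0.538 with an estimated correlation), and at -0.20 with the set as a term. At 24H their median was -0.16 (0.0271, and adjusted p = 0.538 with an estimated correlation), and -0.16 with the set. Mural cell genes of vessel walls were lower at 3D in 16 of 16 members (median -0.33, adjusted p = 6.91e-05, and adjusted p = 0.538 with an estimated correlation), and at -0.22 with the set. Genes of the neocortex and subiculum, next to the hippocampus, were higher at 24H in 14 of 17 (median 0.23, adjusted p = 0.0348, and adjusted p = 0.538 with an estimated correlation), and at 0.23 with the set.

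Nuclear respiratory chain and ribosomal protein genes were higher in the shallower set (medians 0.23 and 0.36, both adjusted p = 0.298 with an estimated correlation), and mitochondrially encoded genes lower (-0.26, and adjusted p = 0.442 with an estimated correlation). Nuclear respiratory chain genes had a median of 0.19 at 3D, -0.18 at 7D and 0.14 at 1M, and of 0.03, -0.06 and 0.02 with the set as a term. Cytosolic ribosomal protein genes had a median of 0.17 at 3D, -0.30 at 7D and 0.19 at 1M, and of -0.0013 at 3D, -0.044 at 7D and 0.0094 at 1M with the set. Plasticity and neurotrophin genes had a median of 0.16 (adjusted p = 0.00235) at 3D and 0.15 (0.000847) at 1M, and of 0.08 (0.207) and 0.05 (0.132) with the set. Under an estimated correlation camera called 0 of the 148 list tests against control, with a lowest adjusted p of 0.192.

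The third pattern weighed is the higher level of immediate early genes in operated groups. The library set is argued against as the whole cause. With the set as a term the list's median was at least 0.893 of its value without it in each of the 4 comparisons. The list was itself higher in the shallower set, by a median of 0.21 (camera adjusted p = 0.0463, and adjusted p = 0.715 with an estimated correlation). A larger share of neurons is argued against, since at 1M with the set the upper quartile of the synaptic list was 0.0104 and the lower quartile of the immediate early list 0.62. Clock phase at collection and surgery cannot be told apart, with a signed fry p of 0.696 at 1M, since output genes of the clock went both ways. Per3 was at 0.45 ± 0.08 (SE) and Hlf at 0.34 ± 0.26, against Nr1d1 at -0.30 ± 0.11, a condition added after the value was seen. Cry1, a gene of the opposite phase, was higher as well, at 0.74 ± 0.11 (edgeR adjusted p = 0.0136 with the set as a term). Handling, maze testing shortly before collection and surgery itself were not tested and stay open. Without the libraries of high choroid plexus score the list's median was 0.20 at 24H, with 24H 4 alone against CON 4 and CON 5. At 7D it was 0.19 and not called, with deeper 7D libraries against those 2 shallower controls, so surgery and set cannot be told apart there. Within the deeper set the medians were 0.78 at 24H and 0.74 at 7D.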
